A study of Mus musculus with 2 samples.

How the data were processed

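Single-cell 3′ RNA sequencing (kit v3.1) was done on sorted DAPI-negative, CD31-positive, CD45-negative cells of skin tumors, with 1 library from 3 pooled tumors for each of 2 genotypes, Ifngr1iProx1 (Cre plus) and Ifngr1WT (Cre minus). The deposited matrices hold counts: raw UMI counts per gene and cell barcode, as whole numbers, for 32285 genes per the file headers. The submitters' processing notes name Cell Ranger 7.0.0 and the mm10 build, and the gene annotation is not given in the sources used here. Genes were taken by the identifiers and symbols in the deposited tables, and coordinates come from GENCODE M21 on mm10, matched by identifier, which gave a position for 99.8% of the genes.

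Groups were taken from the genotype labels. Lists of genes, cell type markers, the rule for genes named singly, the comparisons and their alternatives were fixed before the data were examined. With 1 library per group, no paired analysis, no test and no p-value was possible, and cells were not treated as replicates. Shares have exact Clopper-Pearson 95% intervals. Ratios between libraries have exact conditional binomial intervals on UMI counts, and list medians have intervals from 1000 Poisson draws of every count. None of these covers differences between animals, tumors or sorts.

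Barcodes with at least 500 genes and under 10% mitochondrial UMIs passed, 1782 of 2491 in Cre plus and 1552 of 2502 in Cre minus. In Cre plus 555 and in Cre minus 647 barcodes had under 500 genes, 468 and 733 had 10% or more mitochondrial UMIs, and 234 and 223 had over 50% haemoglobin UMIs. Scrublet, run per library in scanpy 1.11.5, called 3 barcodes in each library. That is 0.18% of the barcodes of both, low for droplet libraries, so it is read as not having worked, and mixed barcodes stayed in. The kept barcodes, 1779 and 1549, carried 63179694 and 70171121 UMIs.

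Both libraries were clustered together with scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and leidenalg 0.10.2. Counts were scaled to 10000 per barcode and log-transformed, and 2000 variable genes were chosen. All genes of the compared lists that are not markers, and Ifngr1, were then left out, which kept 1830. Clustering used 30 principal components, 15 neighbours, shared-neighbour weights and Leiden resolution 1.0. The 21 clusters were named from 24 fixed marker sets: a type needed at least 3 markers detected in at least 10% of the cluster's barcodes, and a cluster stayed unnamed if its 10 leading genes held more markers of another type, or if it was shallow and they held none of its own. Of these 5 were LEC-like, 3 BEC-like and 8 melanoma-like. LEC-like barcodes were clustered again at resolution 0.5.

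UMIs were summed per class and library and scaled to the same total (CPM), and log2 ratios are Cre plus over Cre minus. The 30 lists cover interferon GTPases, interferon signalling, the type I interferon response, MHC class I and class II presentation, inhibitory ligands, chemokines, adhesion, lymphatic capillary, collecting vessel and valve, sprouting, VEGF-C and lymphangiogenic, basement membrane, mitosis, DNA replication, oxidative phosphorylation, mitochondrially encoded, TCA cycle, fatty acid oxidation, glycolysis, NAD metabolism, hypoxia, ribosome biogenesis, unfolded protein response, immediate-early and stress, NF-κB, TGF-β and endothelial-to-mesenchymal, cholesterol synthesis, cell death and Notch genes. Of 724 listed or marker genes 7 had no row in the tables used and were not analysed here (Gbp11, Mx1, Mx2, Cxcl11, Cd99, Ctgf and Cyr61). A list's median used members with at least 50 summed UMIs and was placed among 10000 random lists of the same size, matched on expression. Where a ratio meets a count of 0, a floor of 3 counts is used.

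Genes named singly follow the fixed rule. In LEC-like barcodes these are Ifngr1, Prox1, Lyve1, Pdpn and Flt4, and the 12 highest and 12 lowest genes by the interval bound nearest to 0, among genes with at least 100 UMIs and a UMI in at least 5% of the class's barcodes in a library. Mitochondrial, ribosomal-protein, haemoglobin, X-inactivation, Y-linked and unnamed genes were left out, as were genes whose CPM was under 10% of that in a non-endothelial class with at least 20 barcodes of the library, since these can be free RNA. That removed 132 of 9537 genes in LEC-like and 78 of 7687 in BEC-like barcodes, where the rule took 6 and 6. Up to 4 members with an interval off 0 were named of each list described, and the choice of those lists was made after their values were seen. Of the genes these rules select, 2 are not reported here.

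The alternatives covered the barcode filter, doublet calls, Leiden resolution, variable genes, scaling, a mean over barcodes, thinning to 2000 UMIs, a marker gate, leaving out cycling barcodes and the UMI minimum. Others were chosen after seeing the data: barcodes with at least 0.1% Malat1 UMIs (Malat1-rich) or less (Malat1-poor), ratios corrected for a gene's genomic span, leaving out barcodes with at least 2 markers of stromal, macrophage or T and NK cells, and the marker gate applied only within endothelial clusters. Also chosen then were a count of Cre minus LEC-like barcodes with a UMI of Cxcl9 or class II genes against 1000 draws of UMIs in proportion to depth, a count of macrophage marker UMIs in those with at least 5 such UMIs, against what the macrophage cluster with the fewest markers per such UMI would bring, and intervals from 1000 redraws of whole barcodes, over all and within each Malat1 stratum. The test of the GTPases among Malat1-poor barcodes was added beside the earlier test of both strata, whose wording and outcome were kept, and its bound was written with the values known. An earlier test of free RNA, in melanoma-like barcodes, was dropped because their level of these genes need not be background. Cycling shares count barcodes with UMIs of at least 3 mitosis genes after thinning to 2000 UMIs, and 95 and 12 LEC-like barcodes below that depth were left out.

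The ratio and interval steps were tested on simulated counts at the depth of the LEC-like class, drawn from a Poisson distribution. The intervals assume the same spread. The outcome therefore checks the calculation, not the coverage for UMIs clumped in few barcodes. Intervals covered the true ratio for 96.3% of 11242 genes, 100% of genes changed 2-fold up and 86.0% of genes changed to 0.5-fold were recovered, 3.77% of unchanged genes had an interval off 0, and 0 of 20 unchanged lists fell outside the middle 95% of random lists. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, and figures matplotlib 3.10.9.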

Results

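Endothelial cells were profiled from skin tumors of mice named Ifngr1iProx1 (Cre plus) and Ifngr1WT (Cre minus). Ifngr1 is the ligand-binding chain of the interferon-γ receptor, and Prox1, which the name gives for the Cre, is the transcription factor that sets lymphatic endothelial identity. The tumors were B16F10-OVALBUMIN/VEGFC, a mouse melanoma line that expresses ovalbumin, a model antigen, and VEGF-C, a growth factor of lymphatic vessels. In each genotype 500K cells were implanted in the skin, tumors were taken on day 15, and 3 tumors were pooled and sorted for DAPI-negative, CD31-positive, CD45-negative cells. Each pool gave 1 single-cell 3′ library, so there were no replicates, no test of the genotype was made, and the 95% intervals given in brackets cover counting error only. The Cre plus library held 2491 barcodes and 66704257 UMIs, and the Cre minus library 2502 barcodes and 76967583 UMIs. After filtering, 1779 barcodes with a median of 13630 UMIs were kept in Cre plus and 1549 barcodes with a median of 12451 UMIs in Cre minus.

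The first comparison asked which cell classes the 2 sorts held. Lymphatic endothelial (LEC-like) barcodes made up 50.5% [48.1, 52.8] of the Cre plus library, 898 barcodes, and 16.4% [14.6, 18.3] of the Cre minus library, 254 barcodes, by exact Clopper-Pearson intervals. Blood endothelial (BEC-like) barcodes made up 12.4% [10.9, 14.0] and 17.7% [15.8, 19.7], so that LEC-like barcodes were 80.3% [77.8, 82.5] of both endothelial classes together in Cre plus and 48.1% [43.8, 52.5] in Cre minus. Melanoma-like barcodes, with the pigment-cell genes Dct, Pmel and Mlana, made up 31.0% [28.8, 33.2] and 57.5% [55.0, 60.0], in spite of the CD31 sort. Macrophage and monocyte-like barcodes made up 3.43% and 5.55%, T and NK-like barcodes 0.675% and 0.968%, and platelet-like barcodes 0.281% and 0.452%. An unnamed cluster with pericyte and fibroblast genes (Rgs5, Acta2, Col1a1) made up 1.74% and 1.42%.

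**Figure D1:**
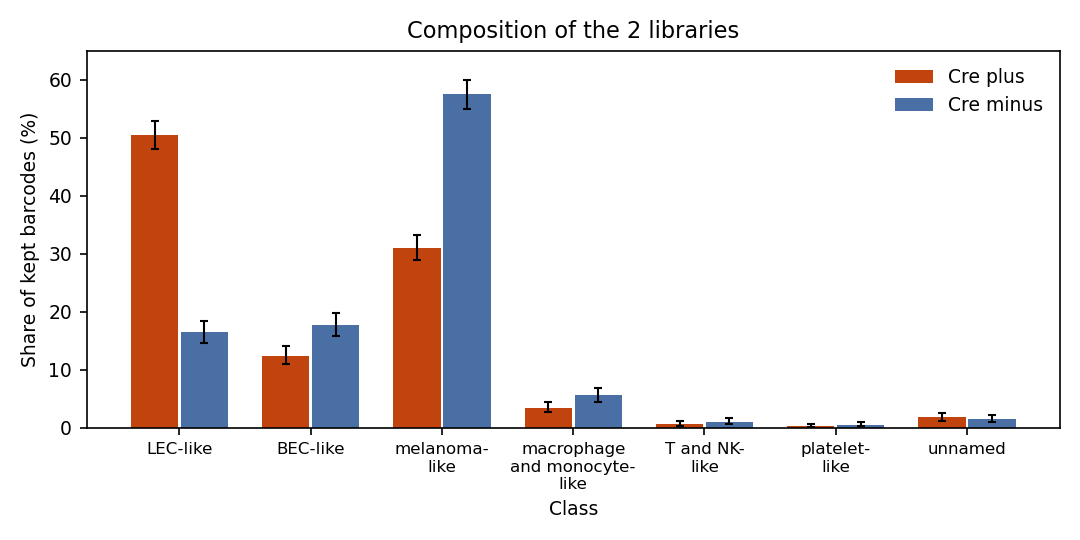
Share of kept barcodes (%, vertical axis) in each class (horizontal axis) for the Cre plus library (1779 barcodes) and the Cre minus library (1549 barcodes). Bars are shares and lines their exact 95% intervals. LEC-like barcodes made up 50.5% of Cre plus and 16.4% of Cre minus.

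The LEC-like barcodes of the libraries also differed in Malat1, an abundant RNA kept in the nucleus. Barcodes with at least 0.1% of their UMIs from Malat1 (Malat1-rich) were 49.9% [46.6, 53.2] of LEC-like barcodes in Cre plus and 16.1% [11.8, 21.3] in Cre minus. In BEC-like barcodes they were 67.4% [60.8, 73.6] and 53.3% [47.2, 59.3], and in melanoma-like barcodes 39.4% and 41.2%. Malat1-rich LEC-like barcodes had a median of 29194 UMIs in Cre plus and 17125 in Cre minus, and Malat1-poor ones 4596 and 4954. The LEC-like class was held by different clusters: clusters 0 and 9, which are Malat1-poor, held 346 and 128 barcodes of Cre plus and 183 and 38 of Cre minus, while the Malat1-rich clusters 1, 12 and 18 held 301, 99 and 24 of Cre plus and 8, 24 and 1 of Cre minus. The difference in LEC-like share was 34.1 percentage points [31.1, 37.0], 42.9 among Malat1-rich and 27.9 among Malat1-poor barcodes.

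Ifngr1 itself (ENSMUSG00000020009, mm10 chromosome 10, 19591949 to 19610229, plus strand) was lower in LEC-like barcodes of the Cre plus library. It had 488 UMIs in Cre plus and 95 in Cre minus, or 28.3 and 43.1 CPM (UMIs scaled to the same total), a log2 ratio of −0.61 [−0.93, −0.27]. In BEC-like barcodes, where Prox1 is not expressed, Ifngr1 stood at 177 and 144 CPM, a log2 ratio of 0.30 [0.14, 0.47]. Within Malat1-rich LEC-like barcodes the Ifngr1 log2 ratio was −1.38 [−1.74, −1.0], and within Malat1-poor ones −0.65 [−1.47, 0.19] from 34 and 22 UMIs. The share of LEC-like barcodes with an Ifngr1 UMI was 30.4% in Cre plus (median 11436 UMIs) and 16.9% in Cre minus (median 5383 UMIs). In melanoma-like barcodes it was 29.2% and 29.6% at median depths of 15873 and 17718 UMIs, with 10.5 and 11.6 CPM. Under a marker gate over all clusters the ratio was 0.35, and under the same gate within endothelial clusters, which keeps most LEC-like barcodes, −0.63. The labels do not say which part of Ifngr1 is deleted, and a 3′ tag can lie outside that part, so the remaining UMIs do not measure how many alleles recombined.

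The main comparison asked how interferon-linked genes in LEC-like barcodes differed between the genotypes. Cxcl9, an interferon-γ induced chemokine that attracts T cells (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079), had 12 UMIs in Cre plus and 267 in Cre minus, 174-fold lower in the Cre plus library with a log2 ratio of −7.44 [−8.41, −6.62]. Few barcodes carried it, since 10 of the 254 in Cre minus held 92.5% of its UMIs. Genes of MHC class II presentation were lower in all 4 measured of 11 listed, with a median log2 ratio of −3.10 [−3.49, −2.69]. Cd74, the invariant chain, stood at 5.68 and 112 CPM (log2 ratio −4.30 [−4.65, −3.96]), H2-Eb1 at −3.28 [−3.99, −2.59] and H2-Ab1 at −2.91 [−3.40, −2.42]. Interferon-induced GTPases, which act against pathogens inside cells, had a median log2 ratio of −0.65 [−0.88, −0.39], at percentile 0 of 10000 random lists matched on expression. Of their 16 measured members 14 were lower, 8 of them by over 1.5-fold, and none was over 1.5-fold higher.

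Guanylate-binding proteins led the GTPases: Gbp2 with 33.7 and 175 CPM (−2.37 [−2.56, −2.19]), Gbp4 (−2.19 [−2.70, −1.65]), Gbp6 (−1.70 [−2.07, −1.32]) and Gbp5 (−1.61 [−2.17, −1.02]). These genes are close paralogs, so that UMIs may be shared among them or lost. Genes of MHC class I presentation, which shows peptides to CD8 T cells, had a median of −0.24 [−0.31, −0.14], also at percentile 0. Among them B2m stood at −0.63 [−0.68, −0.59], the immunoproteasome subunit Psmb9 at −0.69 [−0.89, −0.48] and the proteasome activators Psme1 and Psme2 at −0.56 [−0.67, −0.45] and −0.46 [−0.61, −0.30]. Within Malat1-rich barcodes B2m was at 0.010 [−0.08, 0.10], Psme1 at 0.19 [−0.04, 0.42] and Psme2 at 0.19 [−0.11, 0.50]. The chemokine list had a median of −0.18 [−0.33, 0.10] at percentile 0.125, and its members went both ways. Among Malat1-poor barcodes its median was −1.13 [−1.58, −0.82], with all 7 measured members lower. In Malat1-rich ones it was 0.22 [−0.55, 0.25], which was the value of Ccl21a, a lymphatic marker. Ccl5 stood at −5.32 [−5.85, −4.82], but its 199 UMIs of Cre minus were in 10 Malat1-poor barcodes, and Malat1-rich barcodes had 25 UMIs in Cre plus and 0 in Cre minus. Cxcl10 stood at −1.74 [−2.15, −1.31], and Ccl2, which attracts monocytes, at 0.74 [0.56, 0.92] but −0.96 [−1.21, −0.70] among Malat1-poor barcodes.

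A share of the class II and Cxcl9 signal can be RNA of other cells, so other classes and a macrophage marker were read beside it. Cxcl9 UMIs were in 1.11% of LEC-like barcodes of Cre plus and 9.06% of Cre minus, against 3.81% and 1.91% of melanoma-like barcodes at higher depth. Cd74 UMIs were in 4.68% and 13.8% of LEC-like barcodes, against 47.4% and 30.6% of melanoma-like barcodes and 3.23% and 4.55% of the unnamed pericyte and fibroblast cluster. The macrophage gene Lyz2 stood at 1.80 and 23.1 CPM in LEC-like, 1.55 and 7.04 CPM in BEC-like and 2.06 and 7.49 CPM in melanoma-like barcodes, higher in Cre minus each time. Cxcl9 together with the MHC class II genes summed to 13.7 CPM in Cre plus and 293 CPM in Cre minus LEC-like barcodes, a log2 ratio of −4.42 [−4.64, −4.20], with −3.55 among Malat1-rich and −5.28 among Malat1-poor barcodes and −5.06 without barcodes carrying stromal, macrophage or T and NK markers. With whole barcodes redrawn, its interval was [−5.57, −3.37]. The GTPase median was −0.18 [−0.56, −0.06] at percentile 35.3 among Malat1-rich barcodes and −0.74 [−1.17, −0.58] among Malat1-poor barcodes. Among Malat1-rich barcodes Gbp5 stood at 0.71 [−0.89, 3.01] and Cxcl10 at 0.67 [−0.73, 2.58], wide intervals that include 0. The MHC class I median was −0.013 [−0.13, 0.09] at percentile 61.0 among Malat1-rich and −0.39 [−0.49, −0.33] among Malat1-poor barcodes. Calling LEC-like barcodes by a marker gate over all clusters instead turned the GTPase median to 0.84, class I to 0.45 and class II to 0.40, but 91.2% of the UMIs so gated in Cre minus came from melanoma-like clusters, and the same gate within endothelial clusters gave −0.65, −0.25 and −3.14. That inner gate kept 822 of the 898 LEC-like barcodes of Cre plus and 235 of the 254 of Cre minus. Its values are therefore no independent check.

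**Figure D2:**
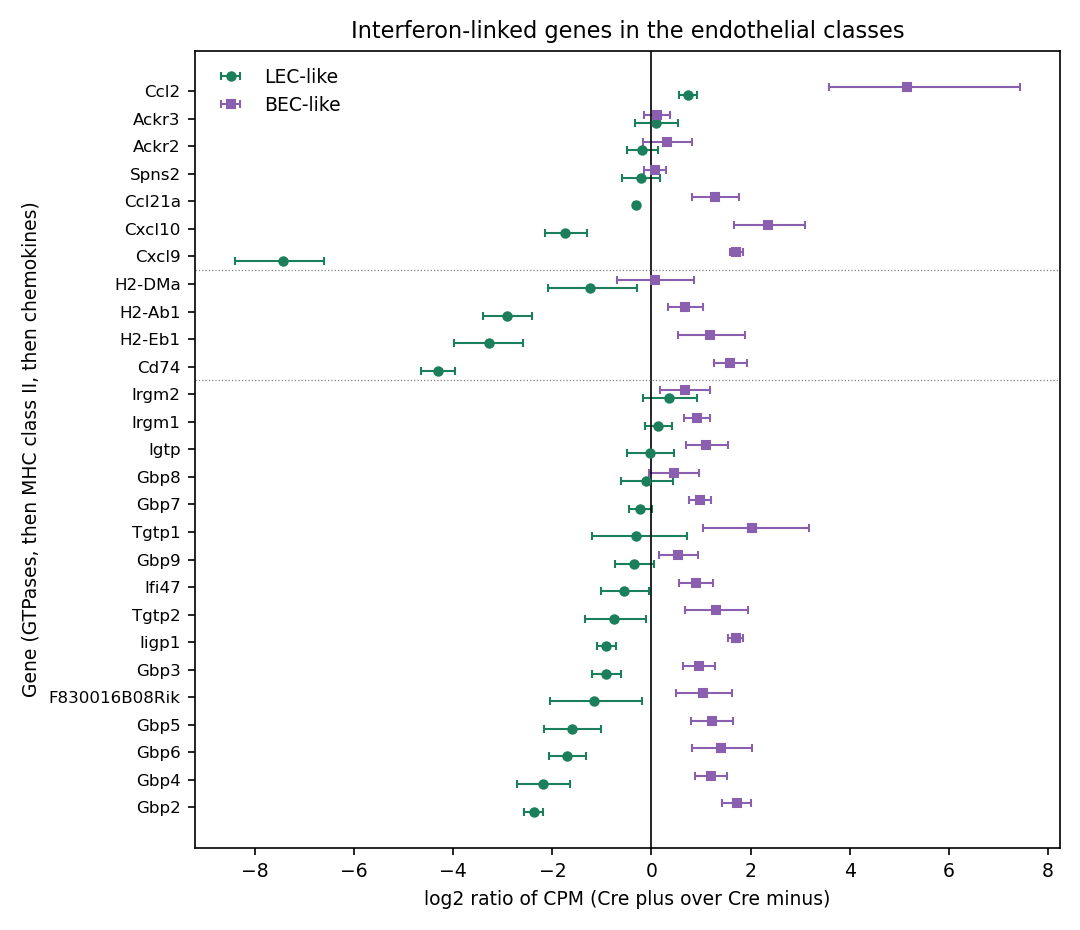
Log2 ratio of CPM, Cre plus over Cre minus (horizontal axis), of interferon-induced GTPases, MHC class II and chemokine genes (vertical axis, in this order from the bottom) measured in LEC-like (circles) and BEC-like (squares) barcodes. Lines are 95% counting intervals. Cxcl9 stood at −7.44 in LEC-like and 1.71 in BEC-like barcodes.

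**Figure D3:**
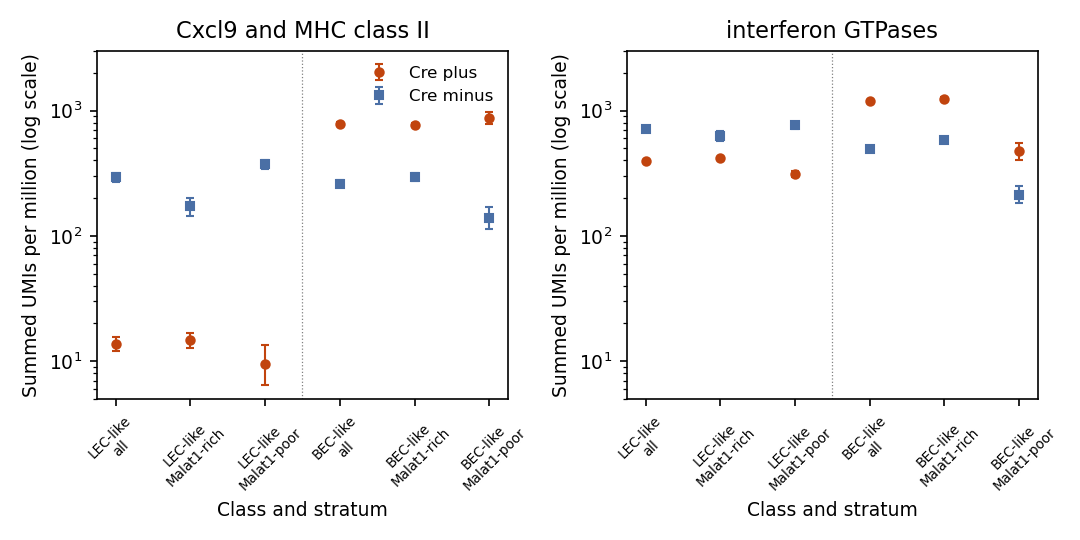
Summed CPM (vertical axis, log scale) of Cxcl9 with the MHC class II genes (left) and of the interferon GTPases (right) per class and Malat1 stratum (horizontal axis) in the Cre plus and Cre minus libraries. Points are sums over all barcodes of the stratum and lines their 95% Poisson intervals. The left panel has 13.7 in Cre plus and 293 in Cre minus over all LEC-like barcodes.

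Over all LEC-like genes with at least 200 UMIs the median log2 ratio was 0.28, so ratios over the whole class are read against that shift, whereas within Malat1-rich and Malat1-poor barcodes it was −0.075 and 0.078. Relative to it the GTPase median was −0.93, class I −0.51 and class II −3.37. Genes of the type I interferon response, which antiviral interferons induce, were not lower: their median was 0.46 [0.37, 0.58], 0.19 relative to the shift, at percentile 99.6, and 22 of 26 were higher in Cre plus. Ifit1 stood at 2.02 [1.45, 2.65], Rsad2 at 1.48 [1.23, 1.74], Oasl1 at 1.66 [0.90, 2.55] and Ifit2 at 0.85 [0.50, 1.21]. Genes of interferon signalling had a median of 0.36 [0.25, 0.47], 0.08 relative to the shift, with Socs3 at 1.40 [0.92, 1.92], Stat2 at 1.06 [0.67, 1.46], Irf9 at 0.80 [0.46, 1.16] and Stat3 at 0.70 [0.46, 0.95]. Among Malat1-rich barcodes the type I median was 0.61 [0.46, 0.84], the signalling median −0.04 [−0.17, 0.15] and Stat3 at −0.11 [−0.38, 0.17].

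Mitosis genes were higher in LEC-like barcodes of Cre plus in all 28 members, 23 of them by over 1.5-fold, with a median of 0.89 [0.77, 1.07], 0.61 relative to the shift, at percentile 100. The spindle motor Kif11 stood at 2.07 [1.39, 2.83], the kinase Plk1 at 1.93 [1.14, 2.85], Mki67 at 1.41 [1.12, 1.71] and Cenpf at 1.21 [0.92, 1.51]. The mitosis median was 0.51 [0.38, 0.72] among Malat1-rich and 1.35 [1.21, 1.64] among Malat1-poor barcodes. DNA replication genes had a median of 0.20, which became −0.07 relative to the shift. Immediate-early and stress genes, which cell handling also induces, had a median of 0.97 [0.83, 1.07], 0.69 relative to the shift, and all 16 were higher, with Fos at 2.26 [1.73, 2.85], Jun at 1.00 [0.78, 1.24] and the heat-shock gene Hspa1b at 2.48 [1.42, 3.81]. NF-κB targets had a median of 0.81 [0.64, 0.99], 0.53 relative to the shift, with Nfkbia at 1.07 [0.85, 1.29] and the leukocyte adhesion gene Icam1 at 1.71 [0.81, 2.79] from 257 and 10 UMIs. Among Malat1-poor barcodes these 2 medians were 0.24 [0.04, 0.49] and 0.22 [−0.20, 0.42], and Icam1 stood at 3.1 and 3.7 CPM from 10 and 5 UMIs.

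Lymphatic identity genes differed less. Prox1, Lyve1, Pdpn, Flt4, Ccl21a, Reln and Mmrn1 are also markers that named the LEC-like clusters and were not left out of clustering. A small difference in these genes is therefore partly built in. Prox1 stood at 554 and 378 CPM (0.55 [0.45, 0.66]), Lyve1 at 0.02 [−0.05, 0.08], the glycoprotein Pdpn at −0.18 [−0.33, −0.04], and Flt4, the receptor of VEGF-C, at 0.13 [0.05, 0.22], which became −0.15 relative to the shift. Within Malat1-rich barcodes Prox1 was at −0.30 [−0.41, −0.19] and Flt4 at −0.46 [−0.57, −0.36]. The lymphatic capillary list had a median of 0.09 [0.03, 0.14], which became −0.19 relative to the shift and was −0.47 [−0.53, −0.42] among Malat1-rich barcodes. Over all LEC-like barcodes Ccl21a, the chemokine that guides dendritic cells to lymphatics, stood at −0.32 [−0.35, −0.29] and Reln at 0.45 [0.35, 0.56]. Mmrn1 stood at 0.25 [0.16, 0.33], which became −0.03 relative to the shift. Among Malat1-rich barcodes these genes reversed, with Ccl21a at 0.22 [0.17, 0.27], Reln at −0.45 [−0.56, −0.34] and Mmrn1 at −0.47 [−0.58, −0.37]. Collecting vessel and valve genes had a median of 0.55 [0.40, 0.75] but −0.16 [−0.33, 0.09] among Malat1-rich barcodes, and VEGF-C and lymphangiogenic genes 0.36 [0.27, 0.44] but −0.33 [−0.42, −0.24].

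Cholesterol synthesis genes were lower in all 18 members, with a median of −0.43 [−0.56, −0.32], −1.07 among Malat1-rich and −0.22 among Malat1-poor barcodes. They were also lower in BEC-like barcodes, at −0.34 [−0.57, −0.22]. The LEC-like minus BEC-like difference was −0.095 [−0.20, 0.13], but −0.63 [−0.82, −0.38] among Malat1-rich barcodes. Lss stood at −1.16 [−1.78, −0.50], Nsdhl at −0.93 [−1.32, −0.51] and Fdps at −0.79 [−0.94, −0.64]. Glycolysis had a median of −0.31 [−0.42, −0.24] but 0.50 among Malat1-rich barcodes. Nuclear genes of oxidative phosphorylation had a median of −0.11 [−0.16, −0.09] over all barcodes. Their median was 0.43 among Malat1-rich and 0.088 [0.06, 0.13] among Malat1-poor barcodes, so it was below 0 in neither stratum. Mitochondrially encoded genes were lower in all 13, with a median of −0.36 [−0.41, −0.33]. Above the shift stood the unfolded protein response (0.47), Notch (0.57), NAD metabolism (0.45), TGF-β and endothelial-to-mesenchymal genes (0.39) and ribosome biogenesis (0.37), but among Malat1-rich barcodes these stood at 0.071, 0.038, −0.079, 0.13 and 0.13. Lists that were above 0 and became negative relative to the shift were sprouting and tip genes (0.25), adhesion (0.23), basement membrane and matrix (0.23), hypoxia (0.20), cell death (0.20), inhibitory ligands (0.18), fatty acid oxidation (0.06) and the TCA cycle (0.06). Among Malat1-rich barcodes adhesion was at −0.37 [−0.50, −0.19] and basement membrane and matrix at −0.23 [−0.32, −0.17]. Hypoxia genes went opposite ways, at 0.50 [0.29, 0.66] among Malat1-rich and −0.24 [−0.42, −0.17] among Malat1-poor barcodes.

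**Figure D4:**
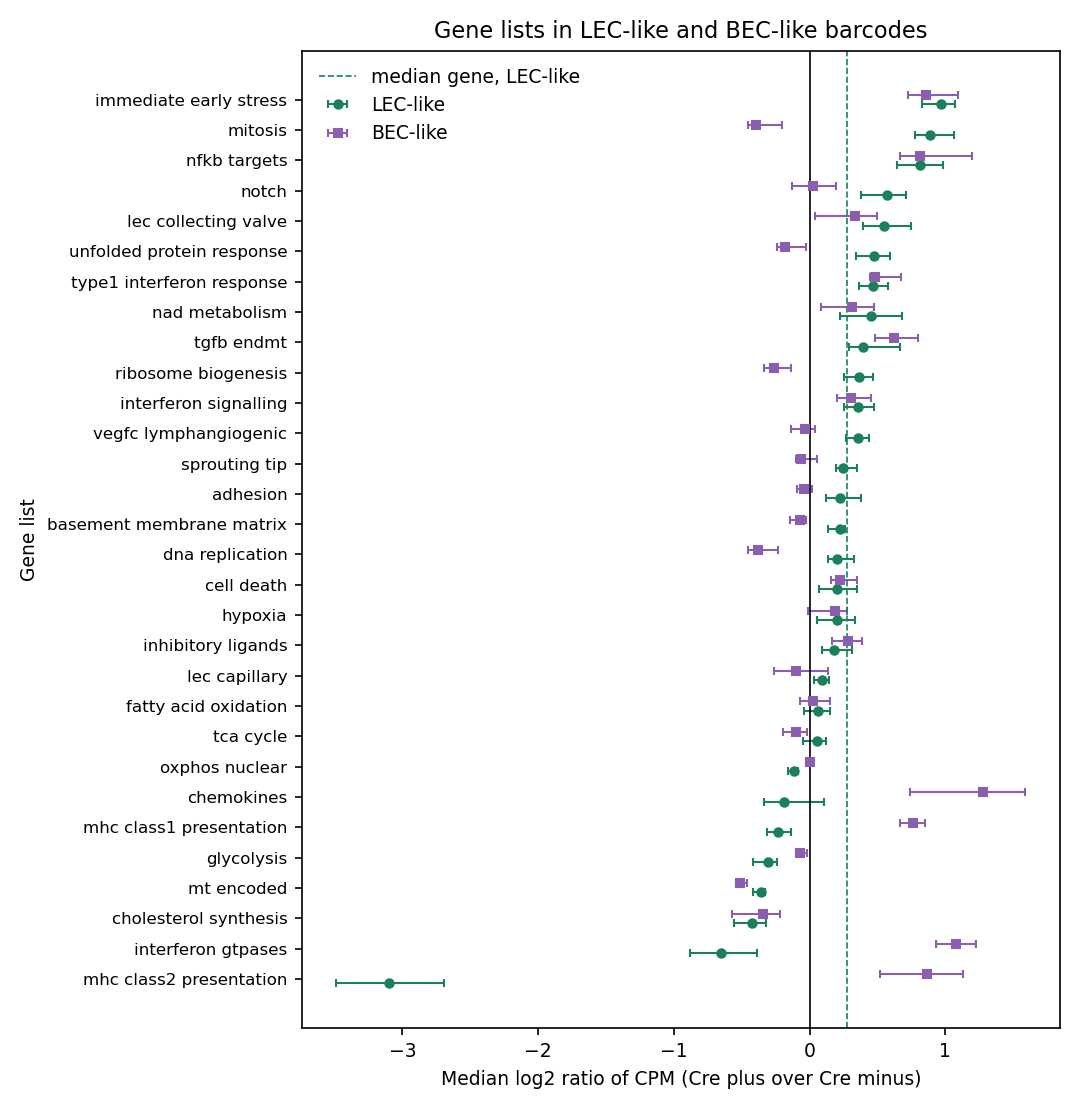
Median log2 ratio of CPM, Cre plus over Cre minus (horizontal axis), of each of the 30 gene lists (vertical axis) in LEC-like (circles) and BEC-like (squares) barcodes. Lines are 95% counting intervals and the dashed line is the median gene of LEC-like barcodes at 0.28. The interferon GTPases stood at −0.65 in LEC-like and 1.08 in BEC-like barcodes.

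Among single genes ranked over the whole LEC-like class, the lower ones included, besides Cxcl9 and the 4 GTPases named above, the complement inhibitor Serping1 (ENSMUSG00000023224, chromosome 2, 84765387 to 84775444) at −2.20 [−2.67, −1.73], the serpin Serpina3g at −1.93 [−2.51, −1.33] and Phf11b at −1.89 [−2.47, −1.29]. The others were Scd1, a fatty acid desaturase, at −2.51 [−2.82, −2.20], Plaat3, a phospholipase, at −2.21 [−2.60, −1.81], Rapgef4, a cAMP sensor, at −2.02 [−2.50, −1.53] and Def8 at −1.59 [−1.96, −1.20]. Higher in Cre plus were the replication-dependent histones Hist1h1b at 2.41 [2.01, 2.84] and Hist1h2ap at 2.17 [1.96, 2.40], which belong to a large paralog family. Robo1, a guidance receptor, stood at 2.15 [1.71, 2.63], the TNF-family ligand Ltb (ENSMUSG00000024399, chromosome 17, 35194439 to 35196320) at 2.21 [1.67, 2.81], Cd24a at 2.76 [1.62, 4.22] and the kinase Sgk1 at 2.01 [1.44, 2.64]. Fosb, Exoc8, Zfp820, Kcnj2 and Cnbd2 had 3, 1, 3, 1 and 3 UMIs in Cre minus, with log2 ratios of 4.54 [2.99, 6.82], 4.52 [2.02, 9.83], 3.30 [1.73, 5.59], 4.08 [1.57, 9.39] and 3.11 [1.54, 5.39]. Ifit1 completed the 12 higher genes.

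BEC-like barcodes of the same sorts served as the class without Prox1, and their interferon-linked genes were higher in Cre plus. The GTPases had a median log2 ratio of 1.08 [0.93, 1.23], with all 16 measured members higher and 14 of them by over 1.5-fold. Gbp2 stood at 1.72 [1.43, 2.02], Iigp1 at 1.70 [1.54, 1.86], Tgtp1 at 2.03 [1.04, 3.17] and Gbp4 at 1.20 [0.87, 1.53]. MHC class I genes had a median of 0.76 [0.66, 0.85], with H2-K1 at 0.94 [0.86, 1.03] and the close paralogs H2-Q6, H2-Q4 and H2-Q7 at 1.55, 1.36 and 1.15. MHC class II genes had a median of 0.87 [0.52, 1.13], with Cd74 at 1.59 [1.26, 1.92], H2-Eb1 at 1.18 [0.53, 1.88], H2-Aa at 1.05 [0.38, 1.76] and H2-Ab1 at 0.68 [0.33, 1.05]. The chemokine list had a median of 1.28 [0.74, 1.59], with Cxcl9 at 616 and 188 CPM (1.71 [1.59, 1.84]), Cxcl10 at 2.34 [1.66, 3.1], Ccl2 at 5.15 [3.58, 7.45] from 141 and 3 UMIs in 12 and 2 barcodes, and Ccl21a at 1.28 [0.82, 1.76]. The list median was the value of Ccl21a, a lymphatic marker, and the part of lymphatic RNA in it was not tested.

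Single adhesion genes were also higher in the BEC-like barcodes of Cre plus, although the adhesion list as a whole had a median of −0.04. Vcam1 and Selp, adhesion molecules for leukocytes, had 160 and 131 UMIs in Cre plus and 4 and 3 in Cre minus (4.92 [3.54, 6.81] and 5.05 [3.47, 7.34]), with UMIs in 26 and 14 of 221 Cre plus barcodes, Icam1 stood at 2.44 [2.0, 2.92] and Jam2 at 0.91 [0.59, 1.24]. NF-κB targets had a median of 0.82 [0.67, 1.20], with Csf1 at 1.91 [1.28, 2.59], but −0.07 among Malat1-poor barcodes. Immediate-early genes had a median of 0.86, but 0.11 [−0.18, 0.40] among Malat1-poor barcodes, with Hspa1b at 2.55 [1.82, 3.38], and Serping1 stood at 2.83 [1.97, 3.83] and Mctp1 at 3.69 [2.81, 4.71]. TGF-β and endothelial-to-mesenchymal genes had a median of 0.62 [0.48, 0.80], but −0.030 [−0.16, 0.16] among Malat1-poor barcodes, and were led by genes that pericytes and fibroblasts express: Acta2 at 701 and 10 UMIs, the former in 15 barcodes, Tagln at 284 and 9, Col1a1 at 198 and 1 (7.23 [4.73, 12.5]) and Col3a1 at 71 and 2 (4.75 [2.84, 7.82]). Col1a1 UMIs were in 0.452% of the 221 Cre plus BEC-like barcodes, which is 1 barcode, so its ratio does not describe the class.

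Lower in BEC-like barcodes of Cre plus were mitosis genes, with a median of −0.39 [−0.45, −0.20] and 21 of 28 members lower, among them Ube2c at −0.92 [−1.16, −0.68], Pbk at −0.85 [−1.33, −0.36], Cdk1 at −0.62 [−0.85, −0.39] and Birc5 at −0.45 [−0.67, −0.23]. The mitosis median was −0.11 [−0.21, 0.03] among Malat1-rich barcodes, Ube2c turned to 1.96 [0.33, 4.0] without cycling barcodes and Pbk to 0.018 as a mean over barcodes. Cycling barcodes were picked by mitosis genes, Ube2c among them, so its value without them does not bear on its lower ratio. Melanoma RNA was also lower in BEC-like barcodes of Cre plus, with Dct at 16.2 and 171 CPM and Pmel at 11.5 and 100 CPM, and its part in these values was not tested. DNA replication genes had a median of −0.38, but 0.15 [−0.17, 0.33] without cycling barcodes, cholesterol synthesis −0.34 and mitochondrially encoded genes −0.51. Among the lowest single genes were Dync1i1 at −1.47 [−1.85, −1.10], Taco1 at −1.26 [−1.59, −0.94], Sntb1 at −1.17 [−1.41, −0.94], Cmss1 at −1.06 [−1.12, −1.01] and Robo1 at −0.97 [−1.09, −0.85], but 1.94 [0.59, 3.40] among Malat1-poor barcodes. Several lists near 0 went opposite ways in Malat1-rich and Malat1-poor barcodes: basement membrane at −0.27 [−0.30, −0.22] and 0.86 [0.67, 0.99], VEGF-C and lymphangiogenic genes at −0.25 and 0.52, adhesion at −0.24 and 0.67, and oxidative phosphorylation at 0.27 and −0.20. The median gene of the class lay at −0.0049, so no shift is subtracted here.

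Set against BEC-like barcodes of the same 2 libraries, which removes a difference common to a library, LEC-like barcodes of Cre plus were lower in GTPases, MHC genes and chemokines. The median difference of the log2 ratios (LEC-like minus BEC-like) was −1.96 [−2.20, −1.48] for the GTPases, with all 16 members negative, −4.03 [−4.61, −3.50] for MHC class II, −1.02 [−1.12, −0.92] for MHC class I, with all 20 members negative, and −1.60 [−2.08, −1.13] for the chemokine list. The chemokine median was the value of Ccl21a, a lymphatic marker, and all 7 measured members were negative. The type I interferon response was at 0.00 [−0.18, 0.14], at percentile 0.4 of random lists, interferon signalling at 0.06 [−0.11, 0.30] and NF-κB targets at −0.03 [−0.26, 0.33], at percentile 2.68. Among Malat1-rich barcodes the type I difference was 0.11, at percentile 91.1. Mitosis was at 1.21 [1.05, 1.42], with all 28 members positive, and DNA replication at 0.63 [0.44, 0.74]. Among Malat1-rich barcodes the GTPase difference was −1.13 and the class I difference −0.70.

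Comparing both classes inside each library gave the level of these genes without the other library. The classes differed in Malat1 mix, and more so in Cre minus. Malat1-rich barcodes were 16.1% of LEC-like and 53.3% of BEC-like ones there, against 49.9% and 67.4% in Cre plus. The medians below are not split by stratum and can reflect that mix. In Cre minus the GTPases were about level over all barcodes, with a median log2 ratio of LEC-like over BEC-like of 0.13 [−0.04, 0.34]. By stratum they were not always level. Summed GTPases stood at 765 CPM in LEC-like and 213 CPM in BEC-like Malat1-poor barcodes, and at 628 and 577 CPM in Malat1-rich ones. In Cre plus they were lower in LEC-like barcodes for all 16 members, with a median of −1.27 [−1.46, −1.09]. MHC class I genes were higher in LEC-like barcodes of Cre minus (0.76 [0.64, 0.84]) and lower in those of Cre plus (−0.46 [−0.49, −0.38]). MHC class II genes were at 1.29 [0.56, 1.93] over 3 genes in Cre minus and −3.63 [−3.82, −3.22] over 6 genes in Cre plus. Mitosis genes were at −0.47 [−0.70, −0.35] and 0.66 [0.59, 0.78], while cholesterol synthesis genes were higher in LEC-like barcodes of both libraries (1.21 and 1.14).

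Within the LEC-like class, re-clustering gave 7 sub-clusters, and the libraries filled them differently, by 33.5 percentage points [28.4, 39.0] summed over sub-clusters and halved. The Malat1-rich sub-cluster 1, led by Ptprm, Magi1, Tcf4 and Prox1, held 37.8% [34.6, 41.0] of Cre plus and 11.8% [8.11, 16.4] of Cre minus LEC-like barcodes. The Malat1-poor sub-cluster 0, led by Cyb5r3, Fth1 and ribosomal-protein genes, held 28.1% [25.1, 31.1] and 50% [43.7, 56.3]. Sub-clusters 4 and 6, which are Malat1-rich and led by the cell-cycle genes Cenpf, Mki67 and Top2a, held 5.23% and 3.90% of Cre plus and 0.787% each of Cre minus, while the Malat1-poor sub-cluster 3 with Stmn1, Pclaf and Birc5 held 9.58% and 15.4%. With every barcode thinned to 2000 UMIs, 20.4% [17.7, 23.4] of LEC-like barcodes in Cre plus and 15.3% [11, 20.5] in Cre minus had UMIs of at least 3 mitosis genes, a difference of 5.13 percentage points [−0.59, 10.1], an interval that includes 0 here but not under some alternatives, such as 8.19 [1.41, 14.3] among Malat1-poor barcodes. Without thinning the shares were 39.0% and 24%, at unequal depth.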

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

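The tests by Malat1 stratum, of free RNA, of macrophage RNA, of stromal or immune barcodes, of redrawn barcodes, of a whole-library difference and of equal damage were chosen only after the results were seen, and that of the cell filter was written down before it was run.

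A contrast between the endothelial classes lay in genes that interferon-γ induces. The median over shared members of the difference in log2 ratio, LEC-like minus BEC-like, was −1.96 for the interferon GTPases, −1.02 for MHC class I and −4.03 for MHC class II. These stood out because the intervals of the classes lay on opposite sides of 0, and with 1 library per group the differences themselves were not tested. It was smaller for the type I interferon response, at 0.19 and 0.49 relative to the median gene of each class, and for interferon signalling, at 0.08 and 0.31. The LEC-like MHC class I median among Malat1-rich barcodes was −0.013 [−0.13, 0.09], so for this list the lower LEC-like value rests on Malat1-poor barcodes.

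Of the genes lower in LEC-like barcodes, Cxcl9 and MHC class II do not follow from an unequal mix of Malat1 strata alone. Their summed ratio was −3.55 [−3.86, −3.24] in the stratum nearer to 0, or [−5.18, −1.55] with whole barcodes redrawn. The redrawn interval lies below 0 but is wide, so how much the mix adds stays open. They do not follow from a difference of the whole library either, with 1.58 [1.48, 1.69] in BEC-like barcodes, or [0.43, 3.15] with whole barcodes redrawn. Free RNA would be spread over many barcodes, as Dct was (73 of 254, with 75 drawn in proportion to depth), but Cxcl9 UMIs of Cre minus were in 23 and class II UMIs in 65, against at least 79 and 101 if 50% of them were so spread. RNA of other cells is not always spread, since Lyz2 was in 24 barcodes against 36 to 46 drawn. The rule for single genes had also left out Cd74 as possible free RNA. Barcodes that also hold macrophages would bring 461 macrophage marker UMIs to the 25 barcodes with at least 5 UMIs of these genes, which hold 86.2% of these UMIs, and 4 were found. Loss of the receptor in Prox1-expressing cells may account for the lower Cxcl9 and class II RNA, as a hypothesis that the data raised, while clumped RNA of another cell type and differences between animals or sorts stay open and untested.

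For the GTPases the mix of strata is not the whole cause, since among Malat1-poor barcodes, where it cannot act, the summed ratio was −1.29, or [−1.97, −0.59] with whole barcodes redrawn, and the list median −0.74 [−1.17, −0.58]. Among Malat1-rich barcodes the summed ratio was −0.60 [−0.73, −0.47], or [−1.45, 0.47] with whole barcodes redrawn, and the list median −0.18 [−0.56, −0.06]. With 41 such barcodes in Cre minus it stays open whether the GTPases differ there, and so how much of the pooled difference the mix makes up. The Malat1-poor test was added last, with its values already known.

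The interferon GTPases were higher in BEC-like barcodes of Cre plus. Barcodes seen to hold stromal or immune cells do not account for it, since the median was 1.55 [1.41, 1.82] without barcodes carrying at least 2 of their markers. That left out 54 of 221 barcodes in Cre plus and 62 of 274 in Cre minus. Barcodes with fewer detected markers stayed in, and deep barcodes reach that limit more easily. The mix of Malat1 strata does not account for it either, since the summed ratio was 1.11 [1.02, 1.19] in the stratum nearer to 0, or [0.36, 1.87] with whole barcodes redrawn, although redrawing in the other gave [−0.23, 2.33]. More interferon-γ around the cells, different animals or a different sort could each give this, and these were not tested.

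LEC-like barcodes with abundant Malat1 were few in Cre minus. Damage that hit all endothelial barcodes of that library alike would shift both classes by the same odds, but the log2 odds ratio was 2.37 in LEC-like and 0.86 in BEC-like barcodes, a difference of 1.51 [0.77, 2.25]. A looser filter, at least 200 genes and under 20% mitochondrial UMIs, gave 47 in Cre minus, against 41 before, and 471 in Cre plus. Removal of barcodes between these filters therefore does not account for it. Barcodes with 20% or more mitochondrial UMIs stayed out under both, so removal of such barcodes was not tested. Among barcodes with at least 500 genes, 154 in Cre plus and 303 in Cre minus had 10% or more mitochondrial UMIs. Damage that falls on lymphatic cells more than on blood endothelial cells, and a biological difference between the genotypes, stay open and untested.

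Before any shift is subtracted, further lists had intervals on opposite sides of 0 in the 2 classes, and none of these differences was tested. Mitosis genes differed by 1.21 and DNA replication genes by 0.63. Relative to the median gene of each class DNA replication was at −0.07 and −0.37 and basement membrane at −0.053 and −0.069, on the same side of 0. Ribosome biogenesis genes differed by 0.58, unfolded protein response genes by 0.50 and basement membrane genes by 0.37. Within the Malat1 strata LEC-like DNA replication was at 0.087 [−0.0045, 0.31] and 0.085 [−0.063, 0.27] and BEC-like mitosis among Malat1-rich barcodes at −0.11 [−0.21, 0.03], intervals that include 0. For ribosome biogenesis, the unfolded protein response and basement membrane at least 1 class changed sign in a stratum.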

How the results depend on the processing

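The strata by Malat1, the correction for genomic span, the gate within endothelial clusters and the removal of barcodes with stromal or macrophage markers were chosen only after the results were seen, as were the lists treated as main results. No paired analysis was possible because there was 1 sample per group. Where no cause is given below, the cause was not tested. Values are log2 ratios, Cre plus over Cre minus, unless given otherwise.

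Most results stayed within their counting intervals. The LEC-like GTPase median did so under 13 alternatives, from −0.82 to −0.49, MHC class I under 11, from −0.30 to −0.17, MHC class II under 13, from −3.37 to −2.87, and mitosis under 10, from 0.79 to 0.96. In BEC-like barcodes the GTPases did so under 13 (0.94 to 1.11), class I under 12 (0.66 to 0.78), class II under 12 (0.59 to 0.89) and NF-κB targets under 16 (0.77 to 1.12). The LEC-like minus BEC-like difference did so under 12 for GTPases (−2.14 to −1.85), 10 for class I (−1.11 to −0.96), 11 for class II (−4.31 to −3.58) and 14 for NF-κB targets (−0.19 to 0.28). Ifngr1 did so under 15 (−0.89 to −0.28), the LEC-like share under 6 (31.4 to 33.9 points), the sub-cluster difference under 5 (31.8 to 34.5 points) and the cycling difference under 10 (1.42 to 8.19 points). LEC-like over BEC-like GTPases did so under 5 in Cre plus (−1.39 to −1.22) and 6 in Cre minus (0.10 to 0.27). Of the genes named singly, 1177 comparisons with an alternative stayed within the interval, 406 left it with the same direction and 48 reversed. The interval of the cycling difference, which includes 0 in the text, lay above 0 with the looser filter (6.14 [0.58, 11]), Leiden resolution 2.0 (6.58 [1.11, 11.2]), clustering on all variable genes (6.72 [1.27, 11.3]) and Malat1-poor barcodes (8.19 [1.41, 14.3]). Genes under 20 UMIs in an alternative, or without UMIs in a library, were given no value.

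The marker gate over all clusters changed most. Its construction shows why: melanoma-like clusters gave 61.2% of the UMIs gated as LEC in Cre plus and 91.2% in Cre minus, and 10.8% and 52.7% of those gated as BEC, and the gate within endothelial clusters gave GTPase medians of −0.65 and 1.04. The gate within endothelial clusters kept most of the same barcodes, so its values were bound to lie near the main ones. Its place among the alternatives counted above adds little. In LEC-like barcodes the gate over all clusters gave GTPases 0.84, class I 0.45, class II 0.40, mitosis 0.16, the unfolded protein response −0.17 and Ifngr1 0.35. In BEC-like barcodes it gave GTPases 1.43, class II −1.52, mitosis 0.018 and NF-κB targets 1.33. The LEC-like minus BEC-like differences were −0.53 for GTPases, −0.18 for class I, 1.98 for class II, 0.36 for oxidative phosphorylation, 0.79 for glycolysis and −0.28 for NF-κB targets. Single LEC-like genes were Pdpn 0.84, Cxcl9 0.89, Gbp2 0.26, Serping1 1.19, Gbp4 0.58, Serpina3g 1.48, Gbp6 0.35, Phf11b 0.24, Gbp5 0.85, B2m 0.33, Psmb9 0.45, Psme1 0.44, Psme2 0.23, Cd74 0.41, H2-Eb1 0.68, H2-Ab1 0.51, H2-DMa 0.0034, Cxcl10 0.092, Ccl21a 2.50, Fos −0.23 and Jun −0.12. Single BEC-like genes were Cd74 −1.33, H2-Eb1 −1.93, H2-Aa −2.46, H2-Ab1 −0.96 and Cxcl10 −0.21. The LEC-like share differed by 24.7 points, and LEC-like over BEC-like GTPases in Cre minus were at −1.0.

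Median-of-ratios scaling, which subtracts the shift of the median gene, gave LEC-like GTPases −0.93, class I −0.51, mitosis 0.61, Flt4 −0.15 and Mmrn1 −0.033, and differences between the classes of −2.24 for GTPases, −1.30 for class I, −0.19 for mitochondrially encoded genes and −0.31 for NF-κB targets. Correction for genomic span gave LEC-like GTPases −0.94, class I −0.49, mitosis 0.61, Flt4 −0.15 and Mmrn1 −0.065, and differences of −1.17 for class I and −0.082 for basement membrane. CPM without mitochondrial and ribosomal-protein genes gave LEC-like class I −0.32.

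Thinning each barcode to 2000 UMIs gave LEC-like GTPases −0.33, class I −0.13 and mitosis 0.73, and BEC-like GTPases 1.27, class I 0.90, unfolded protein response 0.094 and NF-κB targets 0.062. The differences were −2.41 for GTPases, −1.20 for class I, 0.084 for oxidative phosphorylation, −0.043 for mitochondrially encoded genes and 0.64 for NF-κB targets, and LEC-like over BEC-like GTPases in Cre plus were at −1.53. The mean over barcodes gave LEC-like mitosis 0.62, BEC-like GTPases 1.55, class I 0.93, class II 2.79, unfolded protein response 0.17 and Pbk 0.018, differences of −1.34 for class I, −5.98 for class II, 0.012 for oxidative phosphorylation and −0.082 for mitochondrially encoded genes, and −1.59 for LEC-like over BEC-like GTPases in Cre plus.

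Malat1-rich barcodes gave LEC-like GTPases −0.18, class I −0.013, class II −2.08, mitosis 0.51, collecting vessel and valve −0.16, VEGF-C and lymphangiogenic −0.33, oxidative phosphorylation 0.43, glycolysis 0.50 and Ifngr1 −1.38, and BEC-like class I 0.64. The differences were −1.13 for GTPases, −0.70 for class I, −2.67 for class II, 0.14 for oxidative phosphorylation, 0.33 for glycolysis and −0.27 for NF-κB targets. Single LEC-like genes were Prox1 −0.30, Flt4 −0.46, Gbp5 0.71, Stat3 −0.11, B2m 0.010, Psme1 0.19, Psme2 0.19, Cxcl10 0.67, Reln −0.45, Ccl21a 0.22 and Mmrn1 −0.47, and the LEC-like share differed by 42.9 points. Malat1-poor barcodes gave LEC-like class I −0.39, mitosis 1.35, oxidative phosphorylation 0.088 and Ccl2 −0.96, and BEC-like class I 0.25, ribosome biogenesis 0.050, unfolded protein response 0.80, NF-κB targets −0.066, TGF-β and endothelial-to-mesenchymal genes −0.030 and Robo1 1.94. The differences were −0.76 for class I, −0.52 for basement membrane, 0.28 for oxidative phosphorylation, −0.11 for mitochondrially encoded genes and 0.61 for NF-κB targets, and the LEC-like share differed by 27.9 points. MHC class II had too few UMIs for a LEC-like median in this stratum.

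Without barcodes of cycling cells, LEC-like class I was −0.40 and Lss 0.033, BEC-like GTPases 1.60, class I 0.97, DNA replication 0.15, ribosome biogenesis 0.19 and Ube2c 1.96, and the differences −1.41 for class I and −0.045 for ribosome biogenesis. Ube2c is itself among the mitosis genes by which those barcodes were picked. Leaving out barcodes with stromal or macrophage markers gave LEC-like mitosis 0.63 and Pdpn 0.14, BEC-like GTPases 1.55, class I 1.15 and class II 2.11, and differences of −1.42 for class I, 0.11 for oxidative phosphorylation and −0.067 for mitochondrially encoded genes. A minimum of 200 UMIs per gene gave LEC-like GTPases −0.35 and a difference of −1.33, because fewer, more abundant members remained. The stricter barcode filter gave a GTPase difference of −1.48, Flt4 −0.032 and a sub-cluster difference of 41.9 points. Leiden resolution 2.0 gave BEC-like class I 0.62, and without thinning the cycling share differed by 15 points, at unequal depth (medians of 11436 and 5383 UMIs).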

Other observations

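The values in this part were read after the main results were seen, and none of the differences was tested.

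Macrophage and monocyte-like barcodes, 61 in Cre plus and 86 in Cre minus, fell in 2 clusters that the libraries did not share alike, with 48 and 47 barcodes in the larger and 13 and 39 in the smaller. The values below do not separate this from expression within a cluster. The interferon GTPases had a median log2 ratio of 0.78 [0.70, 0.97], with all 15 measured members higher, MHC class I genes 0.46 [0.43, 0.62], with all 21 higher, and the type I interferon response 0.43 [0.35, 0.52]. Ligands of inhibitory receptors, which restrain T cells, had a median of 0.83 [0.60, 0.94]. Cxcl9 stood at 723 CPM in Cre plus and 298 CPM in Cre minus in these barcodes. Mitosis genes were lower at −0.63 [−0.73, −0.34] and cholesterol synthesis genes at −0.67 [−0.90, −0.50]. Lymphatic capillary genes stood at 2.06 [1.90, 2.21] in the same barcodes, with Prox1 at 119 and 13.4 CPM, so RNA of lymphatic cells was present in them, more so in Cre plus. Melanoma RNA went the other way, with Dct at 23 and 1549 CPM and Pmel at 14.6 and 627 CPM, so none of these values can be assigned to macrophages alone.

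Melanoma-like barcodes, 551 and 891, differed less. MHC class II genes had a median of 0.35 [0.15, 0.49] and MHC class I genes 0.18 [0.13, 0.22], while the interferon GTPases stood at 0.03 [−0.08, 0.11]. Among Malat1-poor barcodes class II was at −0.053 [−0.20, 0.15] and the GTPases at −0.21 [−0.41, −0.06], so the class II difference lay in Malat1-rich barcodes. RNA of other cells differed too, with lymphatic capillary genes at 0.84 [0.41, 1.22] and Acta2 at 0.961 and 0.0821 CPM, so these values cannot be assigned to melanoma cells alone. Mitosis genes were at 0.25 [0.21, 0.29] and cholesterol synthesis genes at −0.26 [−0.28, −0.23], with 17 of 18 lower. Vegfc, which the implanted line was made to express, stood at 1367 CPM in Cre plus and 1519 CPM in Cre minus. Ifng, the ligand of the targeted receptor, had 26 UMIs in 12 T and NK-like barcodes of Cre plus and 51 UMIs in 15 of Cre minus, and 7 and 6 of these barcodes had an Ifng UMI. Over all kept barcodes the Y-linked genes Uty and Ddx3y had 1900 and 2191 UMIs in Cre plus and 588 and 680 in Cre minus, and Xist had 2 and 1, as in male animals.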
